A study of Mus musculus with 13 samples.

How the data were processed

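Whole back skin of male C57Bl6 mice at postnatal day 30 was measured on 13 one-colour Affymetrix whole-transcript arrays, 1 per time point from ZT2 to ZT50 at 4 h steps, with RNA of 3 mice pooled per array, per the labels' protocols. Per the submitters' processing notes, Affymetrix Expression Console 1.1.1 and PLIER 2.0 were used, with no role given for either. The deposited values are probe intensity on a linear scale, as their range shows. Whether and how the authors scaled them between arrays is not given in the sources used here, nor is a genome build. The number of arrays limits the precision.

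The table holds 35557 probes. The platform annotation used names 23410 of them, 21789 with 1 gene symbol and 1621 with several, and the other 12147 are unnamed here. Symbols were checked against RefSeq's mouse gene table (GRCm38.p6), used for names only, which held 21698 of the probes with 1 symbol and updated 0. Intensities were taken as deposited and converted to log2(value + 16), so a fold is on that scale and understates the change of dim genes. Probes with 1 symbol and a mean at or above the 25th percentile of all probes (7.61 log2) were kept. Of several probes of a gene, the one with the highest mean stood for it, which concerned 831 genes. This left 16322 genes. The median residual SD around the fitted wave was 0.106 log2.

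The 24 h rhythm was tested in limma 3.58.1 (R 4.3.3) with cosine and sine terms of 24 h period and linear time as covariate over the 13 pools, moderated F and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Amplitude is the height of the wave, in log2, and the fold is from peak to trough. Linear drift was the time term of that fit. Light and dark pools were compared with linear time as covariate. The 12 h wave was tested beside the 24 h one. The cycles were compared by the interaction of cycle with the wave over the 6 pools of the first day and the 6 of the second, leaving out ZT50. Each pool is a separate set of mice, so p-values measure the spread between pools, and the spread between single mice is not seen. Labels carry no replicate numbers that pair pools.

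Gene lists, 32 with 582 genes of which 513 were measured, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. A list's mean centred profile was tested by permuting the 13 times 100000 times, two-sided in effect since the F statistic has no sign, with adjustment over the 31 lists with enough measured members. Upper bounds of list folds are at 95%. Named genes were all measured core clock members, the 12 largest amplitudes among genes called rhythmic with a peak in the light and the 12 with a peak in the dark, up to 6 per direction for light against dark, 10 per direction for drift, 6 for the 12 h wave, the 6 smallest p for the cycles, and up to 4 called members per list. Predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and receptor families of smell were passed over, which left out 2 rhythmic ones. Timp4 was called and falls outside the rule. List members named beyond the rule, such as Fkbp5, Tcap and Cpa3, and the liver genes were chosen after their values were seen.

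Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a 50th percentile filter, all probes, an intensity trend with robust prior, no linear time, cycle as a factor, muscle and adipocyte means as covariates, a fold of at least 1.5, an adjusted p under 0.01, times of day as a factor, 24 and 12 h waves together, a rank test, and leaving out each pool.

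The tests were run on simulated data first, with levels and residual SDs of the 16322 genes and 200 changed genes. For the rhythm, 48.0% of genes with an amplitude of 0.2, 70.0% at 0.3, 90.0% at 0.4 and 96.0% at 0.6 were recovered, with 4.40% false among the calls. For light against dark, 59.7% were recovered at a difference of 0.3 and 88.1% at 0.5. For drift 76.1% were recovered at 0.3 per day, for the 12 h wave 86.6% at 0.3, and for the cycles 20.9% at a difference of 0.4 and 88.1% at 0.8. Noise was drawn independently per gene, so correlated shifts of whole pools are not covered. With 200 changed genes the adjustment is also less strict than with the 23 genes called rhythmic here. The recovery for the rhythm is thus likely overstated. The same goes for light against dark, drift and the 12 h wave, where at most 1 gene passed. Of 100 unchanged lists 4 had a permutation p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.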

Results

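The series followed gene expression in mouse back skin through 2 days and nights. Whole back skin of male C57Bl6 mice at postnatal day 30 was collected every 4 h from ZT2 to ZT50, where ZT counts the hours from lights on, under 12 h of light and 12 h of dark. At this age the hair follicles were in anagen, the growth phase of the hair cycle. RNA of 3 mice per time point was pooled in equal amounts, which gave 13 pools from 39 mice, each measured on 1 array. The 2 h time of day has 3 pools, and 6, 10, 14, 18 and 22 h have 2 pools each. Array medians lay between 440.0 and 483.2 intensity units, and the correlation between any pair of pools over the 16322 genes tested lay between 0.978 and 0.996. The series title concerns the clock gene Bmal1 (Arntl), daily cell proliferation and sensitivity to UVB in the epidermis. Light and dark alternated throughout, so a rhythm here is a daily one, which need not persist in constant conditions. Skin of mutant or irradiated mice was not analysed here.

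The first comparison asked which transcripts followed a 24 h wave. The clock genes led it. Nr1d1, a repressor of Arntl, had a peak-to-trough fold of 5.66 (amplitude 1.25 ± 0.10 log2, SE, 13 pools) and a fitted peak at 7.2 h after lights on. Its intensity was 4164 ± 780 (SD, n = 2) at 6 h and 826 ± 96.7 (SD, n = 2) at 18 h. Dbp, a transcription factor driven directly by the clock, had a fold of 5.85 (amplitude 1.27 ± 0.14, SE) and peaked at 9.7 h, with 2695 ± 61.3 (SD, n = 2) at 10 h and 457 ± 26.9 (SD, n = 2) at 22 h. Arntl had a fold of 1.54 (amplitude 0.31 ± 0.05, SE) and a peak at 22.5 h. The adjusted p was 2.26e-04 for Nr1d1, 0.00228 for Dbp and 0.0287 for Arntl. The call of Arntl held in 5 of the 13 fits that each leave out 1 pool and not with cycle number in place of linear time (adjusted p = 0.0538), no filter (0.0530), all probes (0.0767), the 24 and 12 h waves together (0.0946) or the 6 times of day as a factor (0.719).

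The remaining rhythmic clock genes peaked from late day into early night. Nr1d2, the paralogue of Nr1d1, peaked at 9.0 h with a fold of 3.36. Per3 peaked at 10.8 h with a fold of 2.94, and Tef, a relative of Dbp, at 10.9 h with a fold of 2.24. Per2, which represses the clock's activators together with the Cry proteins, peaked at 13.3 h with a fold of 2.38. These 7 genes passed the test over all genes, out of 20 measured members of the core clock list, and 14 passed adjusted over the list alone. Among the other 7 of these, Hlf had a fitted fold of 1.78 (adjusted p = 0.0750 over all genes), Cry2 1.33 (0.141), Cry1 1.38 with a fitted peak at 16.9 h (0.237) and Clock 1.27 with a fitted peak at 20.8 h (0.452). Per1 had a fitted fold of 1.69, Ciart 1.68 and Bhlhe41 1.33. A second probe of Ciart gave a fitted peak at 9.9 h, beside 10.6 h for the first. Csnk1d, Csnk1e, Bhlhe40, Rora, Timeless and Nfil3 did not pass either test, and the largest fitted fold among them was 1.12, of Nfil3.

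**Figure D1:**
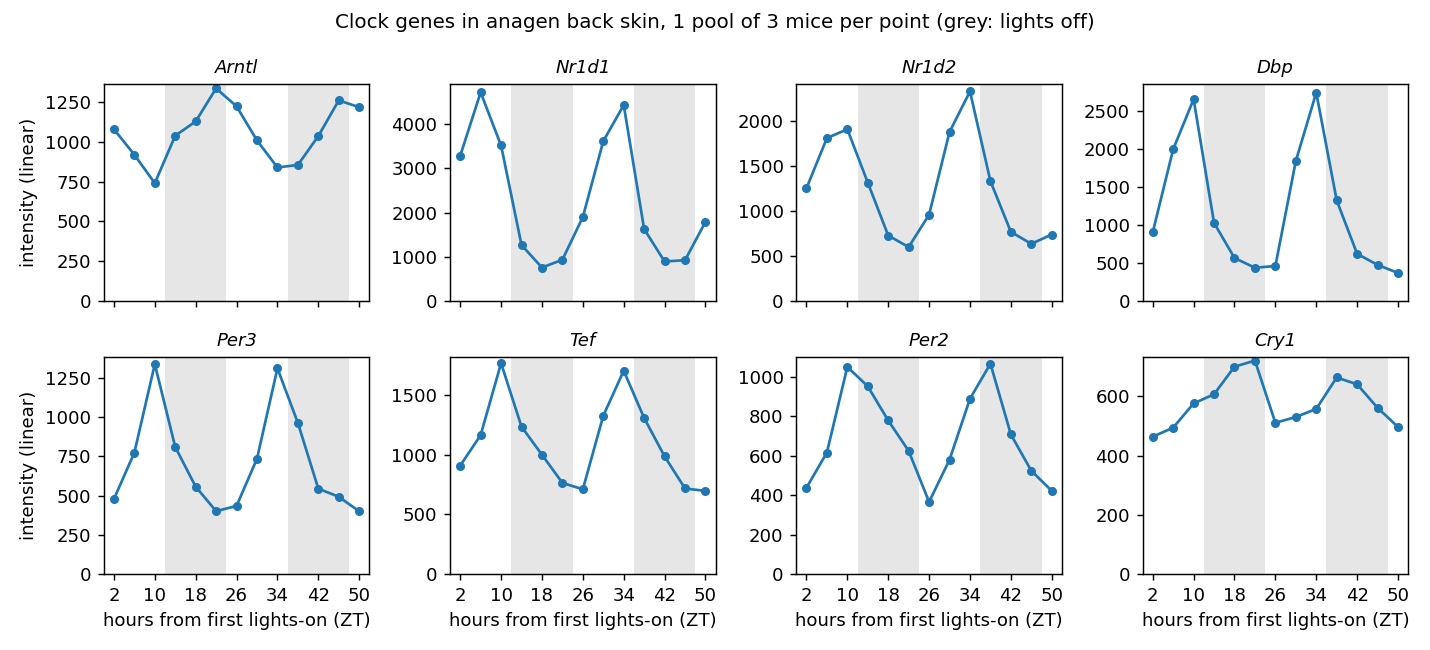
Intensity (linear, vertical axes) of 8 clock genes against hours from the first lights-on, with 1 point per pool of 3 mice and grey bands for lights off. Nr1d1, Nr1d2, Dbp, Per3, Tef and Per2 rose and fell in both days, Arntl peaked late in the night, and Cry1, with a fitted fold of 1.38, did not pass the test over all genes.

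Outside the clock list, a set of genes peaked early in the night. The flavin monooxygenases Fmo1 and Fmo2, which oxidise foreign compounds, had folds of 1.83 and 1.81 and peaks at 14.4 and 15.1 h. Cyp2f2, a cytochrome P450, had a fold of 1.74 and peaked at 15.1 h. Fmo1 was at 2114 ± 329 (SD, n = 2) at 14 h and 1128 ± 64.5 (SD, n = 3) at 2 h. The aldehyde dehydrogenase Aldh3a1 (amplitude 0.29 log2, 14.9 h), the secreted protein gene Angptl7 (1.87-fold, 14.6 h) and Lyve1, a hyaluronan receptor of lymphatic endothelium (1.65-fold, 15.9 h), peaked in the same hours. Fam13a and Tspan4 peaked at 12.0 and 12.5 h with folds of 1.74 and 1.60. Late in the night came Tshr, the thyrotropin receptor, with a fold of 1.80 at 22.7 h, and the matrix protein gene Spon2 with 1.74 at 23.7 h. Aplnr, the apelin receptor, peaked at 2.1 h with a fold of 1.51. Lmod2, which builds actin filaments in muscle, peaked at 9.5 h with a fold of 1.72, and Il31ra, a receptor chain for the itch cytokine IL-31, at 11.9 h with a fold of 1.56. Fmo1, Fmo2, Cyp2f2, Angptl7 and Aplnr passed in 13 of 13 fits that leave out a pool, Lyve1 in 9, Spon2 in 7, Tspan4 and Lmod2 in 5, Tshr and Il31ra in 4, and Aldh3a1 and Fam13a in 3. With the 6 times of day as a factor in place of the wave, only Cyp2f2 and Tspan4 of all these genes passed (adjusted p = 0.0744 for Fmo1), and with cycle number beside that factor none did, nor did Tef (0.0588) and Arntl among the clock genes. Lmod2 did not pass without linear time (0.111). Spon2, Tshr, Aldh3a1, Fam13a and Il31ra did not pass with no filter, with all probes or with the 24 and 12 h waves together. Neither did Tspan4 with no filter or all probes, nor Lyve1 and Lmod2 with all probes. With quantile normalization Fam13a had an adjusted p of 0.0701 and Il31ra one of 0.109. With cycle number in place of linear time, Tspan4 had 0.0537, Tshr 0.0587, Fam13a 0.0706, Il31ra 0.0822 and Aldh3a1 0.102.

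In all, 23 of 16322 genes passed, with folds from 1.49 to 5.85, and 1557 had an unadjusted p under 0.05 where chance gives 816. Of the 23, 14 peaked in the dark, or 60.9% (exact binomial 95% interval 38.5 to 80.3%), and 9 in the light. The interval treats the genes as independent, which genes measured in the same pools need not be. Some peaks lay at the edge, such as Fam13a at 12.0 ± 0.6 h (SE), counted as dark, and Il31ra at 11.9 ± 0.6 h, counted as light. With each array centred on its median the dark share was 46.4% of 28 genes, and without the ZT50 pool 43.8% of 16, so which side held more genes was not settled. With the mean muscle and adipocyte levels as covariates, 2 genes passed, Nr1d1 and Nr1d2, while the amplitudes of the 23 did not shrink (median ratio 1.03). Without the ZT2 pool 15 genes passed, without ZT6 14, without ZT10 14 and without ZT18 13. A rank test passed 0 genes, with 1013 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0979, but its coarse steps limit it. In a run of 2000000 permutations, chosen after the data were seen, Per2, Nr1d2, Fmo1, Fmo2 and Prmt1 shared the smallest p (adjusted p = 0.0653), at which at least 7 genes are needed for an adjusted p under 0.05.

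**Figure D2:**
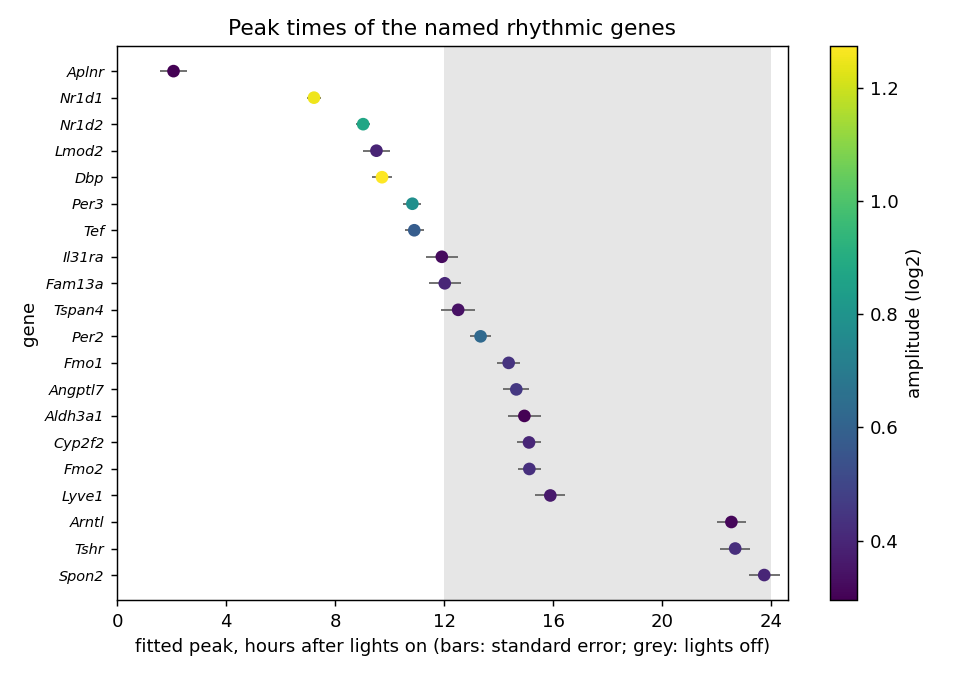
Fitted peak, in hours after lights on (horizontal axis, bars are standard errors, grey is lights off), of the 20 named genes that passed the test for a 24 h rhythm, coloured by amplitude in log2 units. Nr1d1 and Dbp have the largest amplitudes, and 6 genes from Per2 to Fmo2 lie between 13.3 and 15.1 h.

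The second comparison set the 6 pools taken in the dark against the 7 taken in the light. Fam110c was 0.40 ± 0.05 (log2, SE) higher in the dark (limma, adjusted p = 0.0363). Its mean intensity lay between 284.7 and 287.7 at the 3 dark times of day and between 210.6 and 220.8 at the 3 light ones. Its fitted 24 h wave had an amplitude of 0.28 and a peak at 17.9 h, within the dark (limma, adjusted p = 0.0750). Whether a wave or a step between light and dark describes it better was not tested. No other gene passed for light against dark, and 2029 had an unadjusted p under 0.05 where chance gives 816. Genes share the pools, so such a count can lie far from 816 by chance, and it was not compared with other splits of the pools. Nr1d1 was 1.51 ± 0.23 lower in the dark with an adjusted p of 0.0641, and with cycle number in place of linear time it passed (0.0280). Lyve1 was 0.46 ± 0.10 higher in the dark with an adjusted p of 0.297, and Fmo2 0.49 ± 0.12 with 0.324. Fam110c did not pass with quantile normalization (adjusted p = 0.224) or with median centring (0.122), nor without the ZT46 pool (0.0643) or with cycle number in place of linear time (0.113). Its call held in 3 of the 13 fits that leave out a pool.

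The third comparison asked whether gene groups kept a daily rhythm as groups, which bears on the cell proliferation named in the title. The core clock list passed, with a mean peak-to-trough fold of 1.49 and a peak at 10.1 h (permutation p = 0.00017, adjusted p = 0.00527 over 31 lists), though not with the muscle and adipocyte covariates (adjusted p = 0.0597). The genes of G1/S and DNA replication had a mean fold of 1.02 over 29 measured members, with an upper 95% bound of 1.11, and 0 members passed either test (permutation p = 0.832). Those of G2/M and mitosis had 1.05 with an upper bound of 1.21 (29 members, 0 passed, permutation p = 0.685). Nucleotide excision repair, the pathway that removes UV photoproducts, had 1.03 with an upper bound of 1.09 (20 members, 0 passed), other DNA repair 1.02 and cell cycle inhibitors 1.03. Whole skin mixes many cell types, so a rhythm in 1 layer can be diluted in these means.

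Known clock outputs had a mean fold of 1.11 and an adjusted p of 0.0890. Of 21 measured members, Fmo2 and Tspan4 passed over all genes and 7 passed adjusted over the list alone. These include Tsc22d3, a glucocorticoid-induced leucine zipper gene (1.69-fold, 12.4 h), Cys1 (1.41-fold, 13.5 h), Klf9 (1.38-fold, 9.5 h) and Wee1, a kinase that holds back mitosis (1.23-fold, 14.1 h). Without the ZT46 pool this list passed (adjusted p = 0.0203). Of 18 measured glucocorticoid targets, 0 passed over all genes and 9 adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, peaked at 14.3 h (1.49-fold), Zbtb16 at 12.5 h (1.90-fold), Sult1a1 at 14.1 h (1.39-fold), Nfkbia at 7.2 h (1.32-fold), Lcn2 at 14.6 h (1.23-fold) and Angptl4 at 1.5 h (1.49-fold). Tsc22d3, Klf9 and Per1 belong to more than 1 list. The mean of the glucocorticoid targets did not pass (1.14-fold, adjusted p = 0.450).

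Hair and epidermis showed no group rhythm. The hair keratins had a mean fold of 1.04 with an upper bound of 1.19 over 20 members, hair matrix regulators 1.01, follicle stem cell and outer root sheath genes 1.03, basal epidermis 1.01, differentiated epidermis 1.01 and melanocyte genes 1.03, with 0 members passing in any of these lists. Metabolic and stress lists gave 1.05 for oxidative phosphorylation, 1.08 for glycolysis, 1.04 for cholesterol and fatty acid synthesis, 1.04 for oxidant defence, 1.11 for heat shock and cold-inducible genes, 1.05 for immediate early genes and 1.04 for ribosomal proteins. The glucose transporter Slc2a4 and the cold-inducible Rbm3 each passed adjusted over their list alone, and 0 members of these lists passed over all genes. With the muscle and adipocyte covariates, oxidative phosphorylation was the only list to pass (adjusted p = 0.00348).

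Markers of other cells in the skin gave mean folds of 1.14 for sebaceous gland, 1.12 for adipocytes, 1.05 for dermal fibroblasts and matrix, 1.01 for endothelium, 1.04 for macrophages and dendritic cells, 1.13 for mast cells, 1.07 for T and NK cells, 1.06 for neutrophils and inflammation and 1.11 for Schwann cells and nerve. Lyve1 was the 1 endothelial gene that passed over all genes, and Cpa3, a mast cell protease, passed adjusted over its list alone. Among the lists fixed beforehand, skeletal muscle genes had the widest swings, 2.31-fold between the ZT2 and ZT30 pools. Their mean 24 h fold was 1.63 with an upper bound of 2.93 (permutation p = 0.107). Tcap, a sarcomere protein gene, was the 1 muscle list member to pass adjusted over the list alone, with a fitted peak at 10.0 h, close to that of Lmod2. Of the erythroid list too few members were measured for a test.

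**Figure D3:**
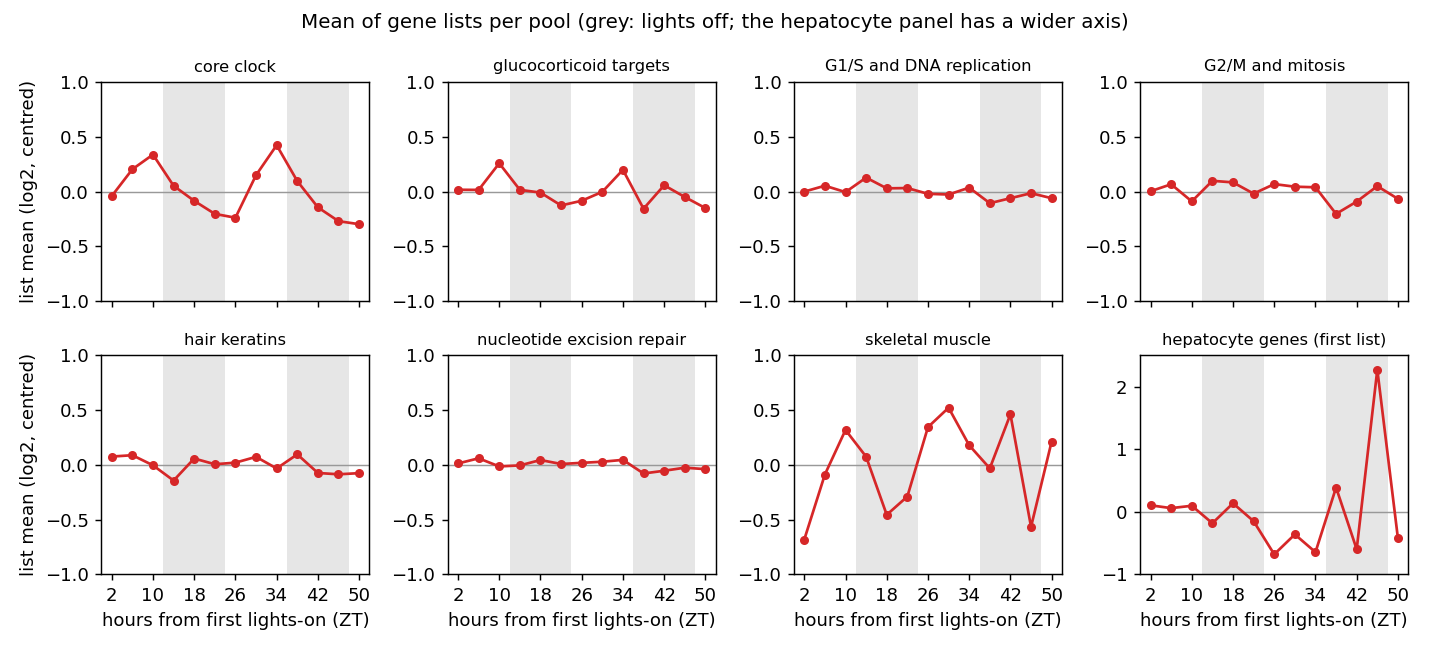
Mean of 8 gene lists in each pool (log2, centred on the mean of all pools) against hours from the first lights-on, with grey bands for lights off and a wider vertical axis for the hepatocyte genes. The core clock list follows both days with a mean fold of 1.49, the proliferation, repair and hair keratin lists stay near 0, skeletal muscle genes range 2.31-fold, and the hepatocyte genes stand high in the ZT46 pool.

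The fourth comparison looked for change across the 48 h. No gene passed over all genes with limma, and no list with the permutation of times. Adjusted over their list alone, 15 members of 11 lists passed, 11 lower with time and 4 higher. They include the G1/S genes Mcm5 (-0.18 log2 per 24 h), Cdt1 (-0.20) and Uhrf1 (-0.15), the clock gene Bhlhe40 (-0.20), and Elovl3 (-0.22) and Mgst1 (0.12) of the sebaceous gland list, named after their values were seen. The lists hold 513 measured genes, and adjustment within a list does not correct for the number of lists. For genes, 1437 had an unadjusted p under 0.05 where chance gives 816, and the smallest adjusted p was 0.246. G1/S and DNA replication genes had a mean slope of -0.06 ± 0.03 log2 per 24 h (SE, 13 pools, permutation p = 0.0455, adjusted p = 0.284), and oxidative phosphorylation genes 0.03 ± 0.01 (permutation p = 0.0284, adjusted p = 0.284).

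A 12 h wave was not detected in any gene with limma. An unadjusted p under 0.05 was found for 290 genes where chance gives 816.

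The last comparison set the rhythm of the first day against that of the second. Of 16322 genes 478 differed, and 0 of these were core clock genes. Nr1d1 came near, with an adjusted p of 0.0522 and fitted peaks at 6.4 h on the first day and 7.9 h on the second. Every other clock gene called rhythmic also had a later fitted peak on the second day. The move was largest in Arntl (21.2 to 23.7 h) and smallest in Per2 (13.19 to 13.25 h). Cry1 and Cry2, not called, had earlier ones, and a shift shared by the clock genes was not tested. The test between days recovered 20.9% of simulated differences of 0.4, so the 0 does not show that the clock was unchanged. The 6 with the smallest p were Aldh1l2, a mitochondrial folate enzyme gene (adjusted p = 0.0333), and Ankrd33, C1qtnf3, the cytokine gene Il17f, the stem cell transcription factor gene Sox2 and the trace amine receptor gene Taar7b (0.0393 each). Aldh1l2 had an amplitude of 0.09 (log2) on the first day and 0.69 on the second, and Sox2 one of 0.27 with a peak at 12.5 h and one of 0.38 with a peak at 20.1 h. Of the 478 genes 88.3% lay below the median level of all tested genes. With quantile normalization or median centring 0 genes passed, with 3442 and 5661 at an unadjusted p under 0.05 beside 4349 as deposited, and without the ZT46 pool 1 did. The count was also 0 without each of the ZT2, ZT10, ZT14, ZT18, ZT22, ZT26, ZT30 and ZT34 pools and 1582 without ZT42.

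Transcripts of liver genes stood high in the ZT46 pool. Albumin (Alb) was at 10035 there and varied from 1027 in ZT42 to 4435 in ZT38 among the other 12 pools. Apoc3, a lipoprotein component, was at 3135 against at most 464, the protease inhibitor gene Serpina1c at 2398 against at most 497, and the urinary protein gene Mup3 at 3598 against at most 525. These genes were chosen after the values were seen. Without this pool 30 genes had a 24 h rhythm, of which 22 were among the 23.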

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

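Of the tests in this part, those on brightness of the ZT46 array and on scaling of dim probes, and both hepatocyte lists, were chosen only after the results were seen.

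A gap between 1 pool and the rest set 7 of 148 groups of values apart, and chance gives about 1 in 20, so a count of this size is near what chance gives. In the gap divided by the range, oxidant defence genes stood at 0.679 in the light (ZT34 highest), Nfil3 at 0.6 in the light (ZT10 lowest), known clock outputs at 0.659 in the dark (ZT14 highest), macrophage and dendritic cell genes at 0.696 in the dark (ZT38 lowest) and Aldh3a1 at 0.674 in the dark (ZT14 highest). The first hepatocyte list stood at 0.656 and the held-out one at 0.727 in the dark, with ZT46 highest in both. The first list was picked for being high in ZT46, so its gap adds no evidence.

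Liver transcripts were high in the ZT46 pool. Brightness of that array is argued against, since 850 genes of like level lay 0.1279 (log2, median, quartiles -0.01 to 0.26) above the other pools while the 18 hepatocyte genes held out of the search lay 0.76 above (quartiles 0.49 to 1.15), and so is time of day, since the ZT22 pool was at or below 7 of the 11 pools of other times. Liver RNA or cells in the pool may be the source, but the test could not settle it: the 0.76 of the held-out genes was short of the 1 set beforehand for this source and above the 0.5 set against it, though 16 of the 18 were highest there. The held-out list had 31 genes, of which 18 were measured. The filter on mean level counted the ZT46 pool, so it could favour held-out genes that were high there. Of the 40 measured hepatocyte genes, 3 lay above the median gene in the other 12 pools and 0 were in lists fixed beforehand, with Alb at 10035, Cyp2c29 at 6793 and Apoa1 at 5318.5 in the ZT46 pool. No biological explanation other than time of day was tested.

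The rhythm differed between the days for 478 genes, with adjusted p of 0.0333 for Aldh1l2 and 0.0393 for Ankrd33, C1qtnf3, Il17f, Sox2 and Taar7b. Scaling of dim probes between arrays is a candidate explanation. Before averaging, each gene's profile was turned to a common direction, which 90.2% of the genes shared as they stood. The mean profile was then turned to correlate positively with the median of the unnamed probes, so the sign of r was fixed in advance. Over the 13 pools Pearson r was 0.742 (permutation p = 0.00372) and Spearman rho 0.758 (permutation p = 0.00375), and r was 0.596 without the 2 farthest pools. With quantile normalization 0 of the 478 genes passed. Their median difference fell from 0.40 to 0.33 (log2) and the residual SD from 0.088 to 0.083, so most of the difference remained when the calls ended. Scaling is thus not shown to be the whole source: with median centring the smallest adjusted p was 0.0512 and genes at an unadjusted p under 0.05 numbered 5661, beside 4349 as deposited. Chance was not excluded, since 3 of the 32 splits that swap days within a time of day gave as many genes, the highest other 1462, which points to a structure of the pools whose source was not tested. A change in the mice between the days stays open and was not tested.

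For the 24 h rhythm, 2 of 100 orders of the times called as many as the real 23, which is under the share set beforehand. The highest other called 789, which points to a structure of the pools whose source was not tested. For light against dark, 3 of 100 splits called as many as the real 1, which is under the share set beforehand, and the highest other called 432. The real count is 1 gene, Fam110c, whose call held in 3 of 13 fits that leave out a pool. The share therefore does not exclude chance and says little on Fam110c. Chance was not excluded for drift, where 14 of 100 orders gave as many genes at an unadjusted p under 0.05 (real 1437, highest other 3243), or for the 12 h wave, where 78 of 100 did (real 290, highest other 3454). For the rhythm counted in that way, 9 of 100 orders reached the real 1557, above the share set beforehand. Chance was thus not excluded for the rhythm on this measure. The real order or split is included in each of these counts.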

How the results depend on the processing

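Chosen after the data were seen were the settings without the ZT46 pool, with the hepatocyte covariate, with an adjusted p under 0.2 and the rank test of 2000000 permutations. The count of 23 rhythmic genes was 15 with no filter and 15 over all probes, 2 with muscle and adipocyte covariates, 12 at an adjusted p under 0.01 and 41 under 0.2, 9 with times of day as a factor and 5 with cycle as the block beside it, and 0 in both rank tests. The longer one had a smallest adjusted p of 0.0653, shared by 5 genes, where its steps need at least 7. These had a score of 60, counting pairs of pools ordered as in the wave less those ordered against it. Of the waves tested, only those peaking at 2 or 14 h allow more, 62, which no gene reached. The 0 thus says little on rhythms with other peaks. The count was 17 with a covariate of muscle genes alone, chosen after the data were seen. In the other settings it lay between 18 and 30, and it was 13 to 30 without each pool in turn. It moved by over 1.5 times without ZT2 (15), ZT6 (14), ZT10 (14) and ZT18 (13). Quantile normalization kept 20 of the 23 genes. With cycle as a block 18 genes were rhythmic, 16 of them among the 23, and Arntl, Tspan4, Tshr, Fam13a, Il31ra, Aldh3a1 and Timp4 did not pass. The 1 light and dark gene was then Nr1d1, lower in the dark (adjusted p = 0.0280), and not Fam110c (0.113). Nr1d1, Nr1d2, Per2, Per3, Dbp, Tef, Fmo1, Fmo2, Cyp2f2, Angptl7 and Aplnr passed in 13 of the 13 fits that leave out a pool, Arntl in 5, Tshr in 4 and Aldh3a1 in 3. The dark share was below the light one at 46.4% with median centring, 46.7% with no filter and 44.4% with cycle as a block, 0 of 2 genes with the covariates, and 43.8 to 64.3% without each pool. The count for light against dark, 1, became 0 with quantile normalization, pseudocount 64, no filter, all probes, the robust prior and without ZT46, 2 with the 50th percentile, the covariates (Fam110c not among them, 0.133) and no linear time, and 0 to 4 without each pool (4 without ZT38). The 478 cycle genes became 0 with quantile normalization, median centring, no filter and all probes, 5 with the 50th percentile, 2201 with the covariates, 1 without ZT46, and 0 to 1582 without each pool (1582 without ZT42; 0 without ZT2, ZT10, ZT14, ZT18, ZT22, ZT26, ZT30 and ZT34). The 12 h count was 1 over all probes and 0 in every fit without a pool. The core clock list (adjusted p = 0.00682 in the draws of this part) had 0.0597 with the covariates, where oxidative phosphorylation passed instead. Lists with a rhythm were 3 with quantile normalization (clock outputs and ribosomal proteins added), 3 without ZT46 (clock outputs and mast cells added) and 1 to 3 without each pool (2 without ZT38). Drift stayed at 0 for genes and lists in each setting run. The cause of these moves was not tested, except that no filter and all probes adjust over more tests. No background level of the arrays was measured here, so what signal over background limits is not known.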

Other observations

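The test of detoxification enzymes was chosen after the rhythmic genes were seen, and so were the reading of its value as open and the reading of the muscle test against the spread of its genes.

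Of the 23 rhythmic genes, 6 peaked between 8 and 12 h and 10 between 12 and 16 h, while 1 peaked between 16 and 20 h and 3 between 20 and 24 h. Timp4, an inhibitor of matrix proteases, was the 1 between 16 and 20 h, at 18.3 h. Among the 1557 genes at an unadjusted p under 0.05 the order differed. In 4 h steps from 0 to 24 h they numbered 204, 302, 211, 374, 421 and 45. Fitted peaks of all genes tested numbered 2398, 3046, 2030, 2724, 4313 and 1811 in the same steps, and no test of clustering was run. Fmo1, Fmo2, Cyp2f2 and Aldh3a1, all enzymes of foreign compound metabolism, lay between 14.4 and 15.1 h. The hypothesis that such enzymes may share an early-night peak beyond the called genes did not pass its test and stays open: the mean of 93 uncalled Cyp, Fmo, Aldh, Gst, Ugt and Sult genes had an amplitude of 0.06 (log2, permutation p = 0.225) with a peak at 15.9 h, and 25 of them had an unadjusted p under 0.05, 15 of these with a peak between 12 and 18 h. Over all genes 1557 of 16322 had such a p. Of the 93 genes 45.2% had a fitted peak between 12 and 18 h, beside 32.5% of all genes tested. The 93 were taken by symbol, so they are not detoxification enzymes alone. They include the folate enzyme gene Aldh1l2 and liver genes such as Cyp2c29, at 6793 in the ZT46 pool and at most 780 in the others. The mean was not tested without these genes or that pool.

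Fitted peaks of muscle genes lay late in the day or at dusk, though of these only Lmod2 passed over all genes. Lmod2 (9.5 h, adjusted p = 0.0238), Tcap (10.0 h, 0.0785) and Mylk4 (12.2 h, 0.0628) had amplitudes of 0.39, 0.43 and 0.87 (log2). A muscle share of the pools that varies with time of day may account for part of this and cannot be told apart from a rhythm within muscle. With the mean of the other muscle genes as covariate the amplitudes kept 0.814 of their size (median, 0.732 to 0.860 over the 3 genes). The median met the 0.8 set beforehand against this explanation. The range of the genes straddles 0.8, with Tcap below it at 0.732, so the test was read as open after its value was seen. Mylk4 then had an adjusted p of 0.0452 and Lmod2 one of 0.287, with its amplitude moving from 0.39 to 0.34. With that covariate 17 genes had a 24 h rhythm, and the median amplitude of the 23 was 1.003 times that without it. Skin of other hair cycle phases was not analysed here.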
